A study of Mus musculus with 39 samples.

How the data were processed

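Gene expression was measured by RNA sequencing of whole-liver homogenates. Per the labels' protocols, livers were flash frozen, RNA was extracted with Trizol and libraries followed a standard Illumina protocol. The library kit, its strand setting, the read filters and the annotation release are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart and were not named. Per the submitters' processing notes, STAR and RSEM were used with the mouse build GRCm38, with no versions given. Per the file headers, each library has RSEM gene-level output for 45706 Ensembl gene IDs. Its expected counts, deposited by the authors, are estimated counts per gene that are not scaled to depth, and 9.8% to 11.36% of the values in a library were not whole numbers. The deposited files also give TPM values, scaled by the authors for gene length and depth, and an effective length in bases. RSEM divides reads that fit several genes by its model, so single values within the Mup, Cyp2c, Saa, Orm, Gbp, Cyp4a, Hba and Tgtp families are uncertain. A merged table of the same counts was not used here.

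Libraries were grouped by the submitters' labels into 8 groups, of 4 libraries for the combined knockdown under AL and 5 for each of the others. Titles of the Pck1 knockdown AL libraries spell the target Pcl1, while their genotype label reads Pck1, which was used. The Pck1 knockdown under IF carries the replicate numbers 1, 2, 3, 5 and 6. No label says that the libraries of a group come from separate animals, so p-values measure the spread between these samples. No batch or date was given. Of 76 pairs of libraries within groups none agreed within sampling noise, the lowest chi-square per degree of freedom being 23.6, so none was taken as a repeat sequencing of another. Each library was counted as 1 replicate, although this check cannot show that libraries come from separate animals. Library totals ranged from 43.74 to 76.24 M. At this depth the genes under the count filter, 29055 of them, held 0.0167% of the counts.

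Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 16651 genes. TMM factors scaled the libraries, with group means from 0.87 in scramble IF to 1.17 in the combined knockdown under IF. A quasi-likelihood model with 1 coefficient per group was fitted to all 39 libraries, and 15 contrasts were tested: IF against AL in each vector, each knockdown against scramble in each feeding state, the combined knockdown against each single knockdown under IF, and for each knockdown the interaction, which is its IF response minus that of scramble. P-values were adjusted by Benjamini and Hochberg within a contrast, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are counts scaled to the TMM-normalised library size (CPM) as mean ± SD. Log2 CPM values used a prior count of 2.

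Before the data were examined, 24 pathway lists and 12 lists of cell type markers were fixed, together with the tests, the alternatives and the rule for naming genes. Of the listed gene symbols 1 was not found, 1 list had fewer than 3 measured members, and the other 35 were tested in each contrast with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Across the contrasts camera made 190 calls on pathway lists and 53 on cell type lists. With an estimated correlation 3 calls held: cholesterol synthesis and de novo lipogenesis in scramble livers and cholesterol synthesis in the Ppara knockdown, each for IF against AL. The lists described for each comparison, and the named genes printed, were picked from these tests after their results had been seen. Ppara and Pck1 are in no list. Genes named for the size of their change had an adjusted p under 0.05, a mean TPM of at least 1 in a compared group and, outside the interactions, no overlap between the groups' libraries. Provisional symbols and immunoglobulin or T-cell receptor segments were left out. They are the 10 largest changes in each direction for scramble IF against AL and the knockdowns against scramble under IF, and the 5 largest in each direction elsewhere. Up to 4 members of each list with the smallest adjusted p were also named. Some genes that this rule takes are not reported here. List members named for their place in a list met the TPM condition but need not meet the adjusted p or overlap condition. Ppara and Pck1 were taken in every contrast without any of these conditions.

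Positions are 1-based GRCm38 coordinates from GENCODE M21, in which 45143 of the IDs had a symbol. The model and list tests were tested on simulated data before use. With 200 genes changed and 16651 tested, the Ppara knockdown against scramble under IF recovered 64.2%, 89.6% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 2.87% of calls false, and DESeq2 68.7%, 92.5% and 100%, with 7.45% false. For the Ppara knockdown interaction recovery was 38.8%, 71.6% and 98.5%, with 3.47% false. For the combined knockdown against scramble under AL, the comparison with 4 libraries in a group, it was 67.2%, 82.1% and 100%, with 5.68% false. A simulated changed list was called and 0 of 100 unchanged lists were. Simulated genes were drawn independently of each other, so this check does not cover lists whose members vary together between libraries. Intervals of list means are bootstraps of 10000 draws over libraries within groups. In 1000 simulations of 5 against 5 values the nominal 95% interval covered the true difference in 89.8%, so these intervals are too narrow.

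Alternatives were RLE size factors, DESeq2 1.42.0, no filter beyond 1 count in any library, a filter at a mean of 1 CPM, offsets from the effective lengths, the replicate number as a block, only the compared groups in the fit, omission of each library in turn, and for the lists a prior count of 0.5, an estimated correlation and limma's fry. Library totals alone as scaling, and omission of 6 libraries (scramble AL 4, Ppara knockdown AL 1, Pck1 knockdown AL 5, Pck1 knockdown IF 5 and 6, combined knockdown AL 4), were added after seeing the data. The 6 libraries were set aside by eye on principal components 1 to 4, not by a rule. By the gap to the nearest library of the group over the group's range (Dixon's 95% critical value), Ppara knockdown AL 1 on component 1 and Pck1 knockdown AL 5 on component 3 (-2.54, the others -27.22 to -24.06) passed. Scramble AL 4 lay outside its group on component 4 (31.32, the others -23.77 to -6.21) without passing, and Pck1 knockdown IF 6 lay within its group on components 1, 3 and 4. Splits of the libraries were refitted on the compared groups alone, with 40 splits per contrast to limit the computing time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.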

Results

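RNA from whole liver was sequenced as 39 libraries from C57BL/6 mice on a Western diet that carried an adeno-associated virus serotype 8 (AAV8) vector, a virus that reaches hepatocytes and here encoded a short hairpin RNA. The hairpin was a scramble control or targeted Ppara, Pck1 or, as the labels name it, the combination. Ppara encodes a nuclear receptor that activates fat oxidation in the fasted liver, and Pck1 encodes the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis. Each vector was studied under ad libitum feeding (AL), with mice killed fed, and under a 5:2 intermittent fasting regimen (IF), with mice killed fasted. Regimen and nutritional state at death therefore changed together in every IF against AL comparison and cannot be separated. There were 5 libraries per group except 4 for the combined knockdown under AL. Total expected counts per library ranged from 43.74 to 76.24 M (M for mega), with a median of 52.65 M. By its title the series asks whether hepatic PPARα and PCK1 carry the effect of the regimen on diet-induced liver disease. The comparisons address the transcriptome of that question: the IF response in each vector, each knockdown against scramble, and the difference between the responses.

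The targeted transcripts were examined first. Ppara (ENSMUSG00000022383; GRCm38 chromosome 15, 85734983 to 85802819, plus strand) was 186 ± 13.1 CPM (mean ± SD, n = 5) in scramble AL livers and 76.3 ± 10.4 in Ppara knockdown AL livers, 40.9% of the scramble mean. Under IF it was 217 ± 19 CPM in scramble and 97.1 ± 4.69 after Ppara knockdown, 44.7% of the scramble mean. The log2 fold changes were -1.29 ± 0.13 (SE, adjusted p = 9.88e-08) under AL and -1.16 ± 0.13 (adjusted p = 2.04e-07) under IF. Every Ppara knockdown library lay below every scramble library of the same feeding group. Ppara was also lower in the Pck1 knockdown, at 112 ± 10.2 CPM under AL and 80.8 ± 21 under IF (log2 fold change -1.43 ± 0.13, adjusted p = 1.68e-11). By the deposited TPM, which carries no TMM factor, that fall was smaller. Mean TMM factors were 0.878 in scramble AL and 1.125 in Pck1 knockdown AL livers, so CPM and TPM differ in scaling as well as in length correction. Under AL, libraries ranged from 60.5 to 77.46 TPM after Pck1 knockdown and from 79.34 to 96.7 in scramble. Under IF the ranges were 41.51 to 77.01 after Pck1 knockdown and 102.43 to 121.01 in scramble. Ppara knockdown libraries under IF lay at 37.35 to 45.57 TPM. Pck1 (ENSMUSG00000027513; GRCm38 chromosome 2, 173153048 to 173159273, plus strand) was 1831 ± 578 CPM in scramble AL and 434 ± 148 in Pck1 knockdown AL livers, 23.7% of the scramble mean. Under IF it was 3528 ± 1440 CPM in scramble and 861 ± 316 after Pck1 knockdown, 24.4% of scramble. In the combined knockdown Ppara stood at 38.1% of scramble under AL and 23.2% under IF, and Pck1 at 38.9% and 26.9%. The Ppara knockdown changed Pck1 by 0.25 ± 0.28 on the log2 scale under IF (adjusted p = 0.689), which did not pass the threshold. That value was 0.439, 0.393, 0.11 and 0.158 without scramble IF replicates 1, 2, 3 and 4.

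**Figure D1:**
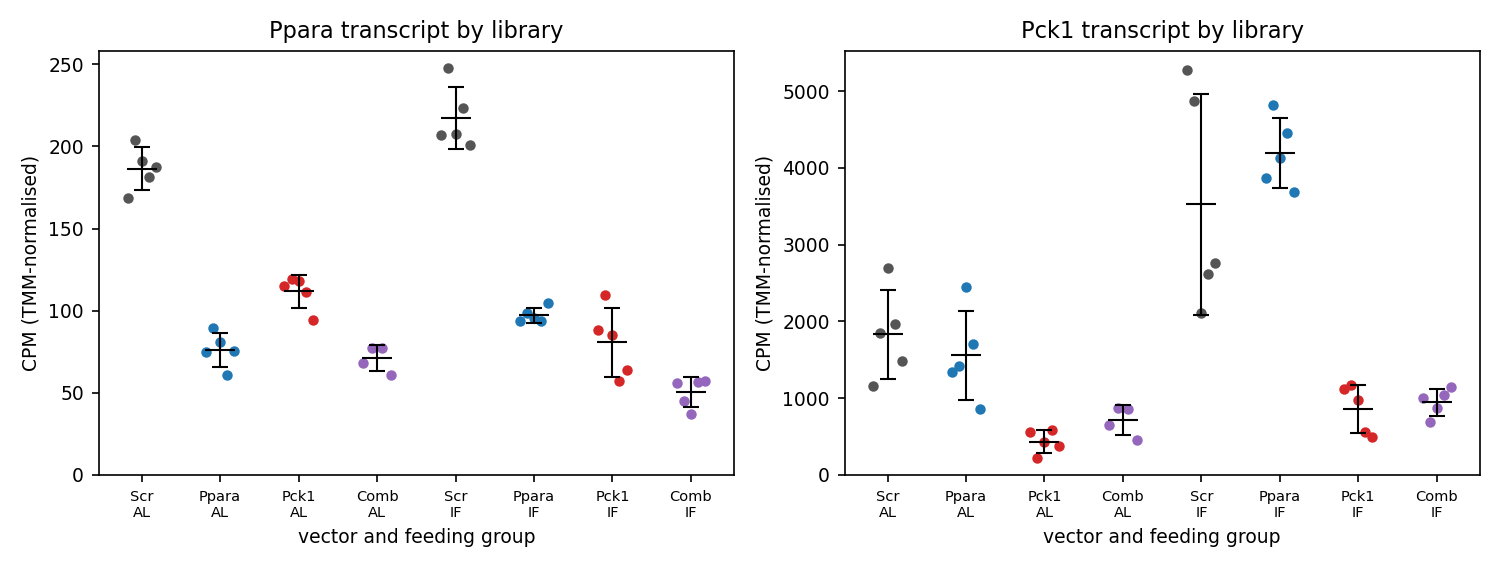
Ppara (left) and Pck1 (right) transcript in TMM-normalised CPM, by vector and feeding group. Dots are libraries, horizontal marks are group means and bars are 1 SD. The mean Pck1 level was 3528 CPM in scramble IF livers and 861 CPM in Pck1 knockdown IF livers.

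Principal component 1 of log2 CPM held 49.1% of the variance and separated the livers given the Pck1 or combined vector from those given the scramble or Ppara vector. Component 2 held 11.1% and separated IF from AL in each vector. Ppara knockdown AL replicate 1 lay at -4.59 on component 1, while the other 4 libraries of its group lay between -57.48 and -45.85.

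**Figure D2:**
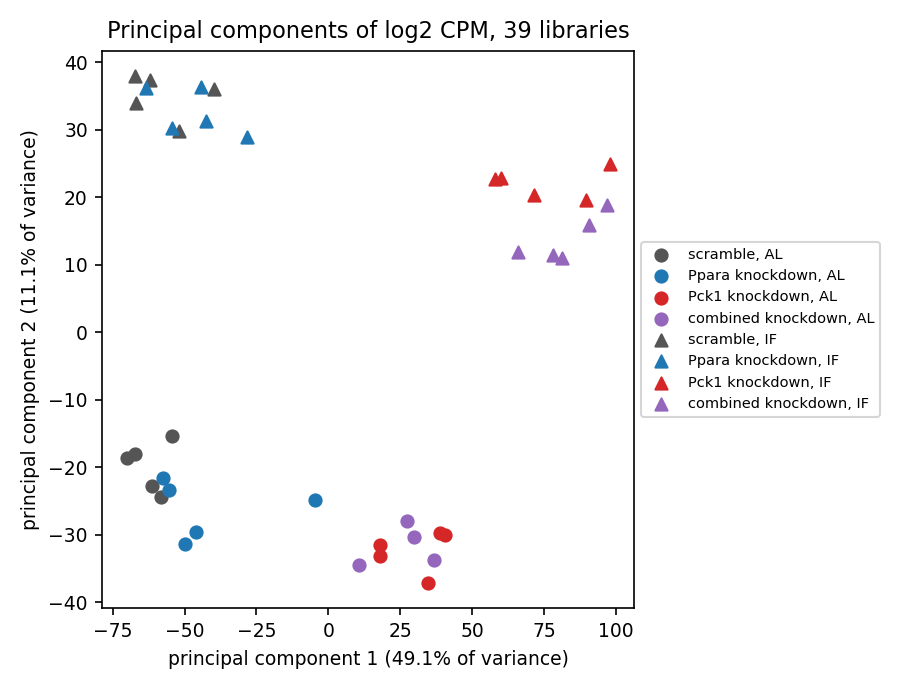
Principal components 1 and 2 of log2 CPM over the genes tested, 39 libraries. Colours are vectors, circles are AL and triangles are IF libraries. Livers given the Pck1 or combined vector lie at 10.58 or above on component 1, and all others at -4.59 or below.

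In scramble livers the IF regimen, sampled fasted, raised transcripts of fat oxidation and lowered those of lipid and sterol synthesis. Among PPARA target genes 17 of 22 measured members rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 9.86e-15, adjusted p = 0.0817 with an estimated correlation). Cyp4a14, a microsomal fatty acid omega-hydroxylase, went from 16.4 ± 11.1 to 4961 ± 1580 CPM (log2 fold change 8.24 ± 0.69, adjusted p = 7.84e-11). Ehhadh, a peroxisomal beta-oxidation enzyme, went from 359 ± 53.5 to 2075 ± 414 CPM (2.53 ± 0.22, adjusted p = 1.18e-10). Mitochondrial fatty acid oxidation genes rose in 15 of 18 cases (15 adjusted over the list alone; camera adjusted p = 2.77e-16, adjusted p = 0.0963 with an estimated correlation). Acadm changed by 1.07 ± 0.10, adjusted p = 3.7e-10. Within gluconeogenesis and amino acid catabolism 12 of 28 members rose (12 adjusted over the list alone; camera adjusted p = 0.000261, adjusted p = 0.607 with an estimated correlation). That count was 7 without scramble IF replicate 1 and 7 without scramble IF replicate 4. Of the largest single increases, Lepr, the leptin receptor, rose by 4.47 ± 0.66 (adjusted p = 3.91e-06) and the metallothionein Mt2 by 5.16 ± 0.64 (adjusted p = 1.97e-07).

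De novo lipogenesis genes fell in 18 of 22 cases in scramble livers (20 adjusted over the list alone; camera adjusted p = 4.26e-21, adjusted p = 0.0137 with an estimated correlation). Fasn, the fatty acid synthase, went from 1402 ± 139 to 97 ± 16.7 CPM (log2 fold change -3.85 ± 0.35, adjusted p = 4.6e-10). Srebf1, a transcription factor of lipogenesis, changed by -2.68 ± 0.22, adjusted p = 6.62e-11. Cholesterol synthesis genes fell in 20 of 24 cases (21 adjusted over the list alone; camera adjusted p = 7.14e-25, adjusted p = 0.00953 with an estimated correlation). Idi1, an isoprenoid isomerase, changed by -3.25 ± 0.25, adjusted p = 1.43e-11. Seen over all genes, 3839 of 16651 differed between IF and AL in scramble livers, 1912 higher and 1927 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Markers of other cell types moved in the same comparison. Erythroid markers rose in 4 of 5 cases (4 higher and 1 lower adjusted over the list alone; median 1.13; camera adjusted p = 0.0314, adjusted p = 0.61 with an estimated correlation). That list call was lost without scramble AL replicate 2, 4 or 5 or scramble IF replicate 5 (adjusted p = 0.0692, 0.0689, 0.0549 and 0.0769), and without 6 libraries set aside by eye after seeing the data (adjusted p = 0.0761). Sinusoidal endothelial markers rose in 2 of 10 (2 adjusted over the list alone, camera adjusted p = 0.0294, adjusted p = 0.703 with an estimated correlation). That count was 0 with library totals alone, 0 without scramble AL replicate 3 or 5 or scramble IF replicate 3, 4 or 5, and 1 without scramble AL replicate 1 or 4. The list call was lost with fry (adjusted p = 0.0549) and without scramble AL replicate 3 or scramble IF replicate 5 (adjusted p = 0.0665 and 0.0769). The Cyp4a genes are close paralogs, and how reads shared between them were divided makes their single values uncertain.

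The IF response was present in the Ppara knockdown. PPARA target genes rose in 16 of 22 cases with 1 lower (18 and 1 adjusted over the list alone; camera adjusted p = 3.18e-14, adjusted p = 0.0901 with an estimated correlation). Mitochondrial fatty acid oxidation genes rose in 14 of 18 (15 adjusted over the list alone; camera adjusted p = 5.93e-14, adjusted p = 0.164 with an estimated correlation). Cyp4a14 went from 2.61 ± 2.02 to 1714 ± 583 CPM (log2 fold change 9.36 ± 0.73, adjusted p = 1.58e-11). Fasn went from 2186 ± 1280 to 90.1 ± 12.1 CPM (-4.60 ± 0.37, adjusted p = 2.77e-11). Of other cell types, erythroid markers rose in 4 of 5 (4 adjusted over the list alone, median 1.51, camera adjusted p = 0.00721, adjusted p = 0.424 with an estimated correlation), sinusoidal endothelial markers in 6 of 10 (6 adjusted over the list alone, median 0.54, camera adjusted p = 0.00134, adjusted p = 0.424 with an estimated correlation) and stellate cell markers in 5 of 10 (5 adjusted over the list alone, median 0.55, camera adjusted p = 0.00184, adjusted p = 0.457 with an estimated correlation). The test of the difference between the responses, the interaction, called 3 genes. Cgref1 responded more in the knockdown (1.56 ± 0.30, adjusted p = 0.0443) and Tmem98 (-1.12 ± 0.20, adjusted p = 0.0443) and Slc52a2 (-0.61 ± 0.12, adjusted p = 0.0443) less. No PPARA target gene passed this test (edgeR), adjusted over all genes or over the list alone, while 1120 of all genes had an unadjusted p under 0.05 in edgeR and DESeq2 called 30 of all genes. The count of 3, and with it all of these calls, fell to 0 with no count filter, with effective-length offsets, with library totals alone and with only the compared groups in the fit. It was 6 with the filter at a mean of 1 CPM and 27 without the 6 libraries set aside. It also fell to 0 without any 1 of scramble AL replicates 1, 2, 4 and 5, Ppara knockdown AL replicates 2 and 4, scramble IF replicates 3 and 5 and Ppara knockdown IF replicates 2, 3 and 4. It was 1 without Ppara knockdown AL replicate 5 or scramble IF replicate 2, where the Cgref1 and Slc52a2 calls were lost. It was 5 without Ppara knockdown IF replicate 5, 8 without scramble IF replicate 1 and 10 without Ppara knockdown AL replicate 1 or 3. The Cgref1 call was also lost without scramble AL replicate 3, and the Slc52a2 call without scramble IF replicate 4 or Ppara knockdown IF replicate 1 or 5. The mean log2 response of the list was 1.86 in scramble and 2.11 in the knockdown, and their difference was 0.25 (nominal 95% bootstrap interval over libraries -0.17 to 0.65). In total 4490 genes differed between IF and AL in the Ppara knockdown, 2177 higher and 2313 lower. Across genes, the log2 responses of scramble and Ppara knockdown livers correlated with Pearson's r = 0.642 and Spearman's rho = 0.641, a value over genes, which are not independent replicates.

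Lower Ppara was accompanied by lower fat oxidation transcripts in both feeding states. Against scramble under AL, mitochondrial fatty acid oxidation genes fell in 11 of 18 cases (16 adjusted over the list alone; camera adjusted p = 4.93e-22, adjusted p = 0.0835 with an estimated correlation). PPARA target genes fell in 8 of 22 (12 adjusted over the list alone; camera adjusted p = 5.9e-16, adjusted p = 0.0835 with an estimated correlation). Etfdh, which passes electrons from fat oxidation to ubiquinone, changed by -0.68 ± 0.09, adjusted p = 2.21e-05. Cyp4a10 changed by -3.01 ± 0.51, adjusted p = 0.000779. These counts were 7 oxidation genes without scramble AL replicate 4, Ppara knockdown AL replicate 1 or replicate 2. They were 5 target genes with library totals alone as scaling, and 5 without scramble AL replicate 2 or 5 or Ppara knockdown AL replicate 2, 4 or 5. Acute phase genes were higher in the Ppara knockdown under AL, 12 of 20 of them past the threshold (14 adjusted over the list alone; camera adjusted p = 4.28e-13, adjusted p = 0.184 with an estimated correlation). Lcn2, lipocalin 2, went from 7.82 ± 1.17 to 91.2 ± 120.0 CPM (3.54 ± 0.58, adjusted p = 0.000474). That count was 5 without Ppara knockdown AL replicate 4, whose mean log2 CPM over the list was 9.40 against 7.82 in the next library, and 6 without scramble AL replicate 5. The Lcn2 change was 2.27 without Ppara knockdown AL replicate 4. Kupffer cell markers were higher in the same comparison in 6 of 10 cases (9 adjusted over the list alone; camera adjusted p = 2.76e-08, adjusted p = 0.187 with an estimated correlation). Their count was 3 with library totals alone as scaling, 0 without the 6 libraries set aside, 0 without scramble AL replicate 1 or Ppara knockdown AL replicate 1, 1 without scramble AL replicate 4 or 5 and 2 without scramble AL replicate 2 or 3 or Ppara knockdown AL replicate 2. With only the compared groups in the fit, 6 of all genes were higher and 46 lower. Acute phase and Kupffer cell genes that were higher in that fit can therefore number at most 6. Camera also called higher inflammatory genes (median log2 fold change 1.12, camera adjusted p = 3.1e-08, adjusted p = 0.397 with an estimated correlation), macrophage markers (0.47, camera adjusted p = 0.0174, adjusted p = 0.683 with an estimated correlation), T and NK cell markers (0.76, camera adjusted p = 0.0174, adjusted p = 0.649 with an estimated correlation) and neutrophil markers (0.84, camera adjusted p = 0.0028, adjusted p = 0.397 with an estimated correlation). The macrophage and the T and NK cell calls were lost without scramble AL replicate 4 (adjusted p = 0.178 and 0.133) or Ppara knockdown AL replicate 1 (0.404 and 0.318), which stood apart from its group in macrophage markers. The neutrophil call was lost without scramble AL replicate 4 (adjusted p = 0.076). With fry none of the inflammatory, macrophage, T and NK cell and neutrophil calls held (adjusted p = 0.0651, 0.332, 0.271 and 0.0697). The macrophage, T and NK cell and neutrophil calls were also lost without the 6 libraries set aside (adjusted p = 0.976, 0.819 and 0.238).

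Under IF the Ppara knockdown lowered 15 of 18 mitochondrial fatty acid oxidation genes (17 adjusted over the list alone; camera adjusted p = 5.58e-17, adjusted p = 0.382 with an estimated correlation). It lowered 7 of 22 PPARA target genes (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.93e-08, adjusted p = 0.625 with an estimated correlation). Ehhadh went from 2075 ± 414 to 689 ± 115 CPM (log2 fold change -1.59 ± 0.21, adjusted p = 3.53e-06). Vnn1, a pantetheinase, changed by -1.46 ± 0.27, adjusted p = 0.000455. Slc16a11, a monocarboxylate transporter family member, changed by -1.68 ± 0.18, adjusted p = 2.04e-07. Among the genes that rose, Acacb, the acetyl-CoA carboxylase whose product inhibits mitochondrial fat import, went from 52.7 ± 13.5 to 139.9 ± 19.5 CPM (1.41 ± 0.24, adjusted p = 0.000141). Cfd, complement factor D and a marker of fat cells, was 45 ± 75.4 CPM in scramble and 2.2 ± 2.66 in the knockdown (-4.34 ± 1.10, adjusted p = 0.011). Without scramble IF replicate 3 the change was -2.38 (adjusted p = 0.164), and with only the compared groups in the fit the adjusted p was 0.0832. Camera also called lists higher under IF, with median log2 fold changes of 0.64 for inflammatory genes (camera adjusted p = 0.00724), 0.38 for stellate cell (0.00645), 0.36 for Kupffer cell (0.0308) and 0.63 for T and NK cell markers (0.037) and 0.21 for acute phase genes (0.037). At most 1 member of each of these 5 lists passed the threshold. None of the 5 calls held with an estimated correlation (adjusted p = 0.986 for each) or with fry (adjusted p = 0.32 to 0.598). The inflammatory call was lost without Ppara knockdown IF replicate 1 (adjusted p = 0.108). The Kupffer cell call was lost without scramble IF replicate 3 or Ppara knockdown IF replicate 1 or 5 (adjusted p = 0.163, 0.201 and 0.0596), and the T and NK cell call without these or scramble IF replicate 1 (0.072, 0.231, 0.0723 and 0.0751). The acute phase call was lost without scramble IF replicate 3 or 4 or Ppara knockdown IF replicate 1, 2 or 3 (adjusted p = 0.0873, 0.124, 0.149, 0.0718 and 0.0705). The Ppara knockdown changed 354 genes under AL (158 higher, 196 lower) and 1045 under IF (298 higher, 747 lower). With library totals alone as scaling, 55.9% of the AL calls and 54.6% of the IF calls were higher, against 44.6% and 28.5% here. The AL count was 52, of which 11.5% were higher, when only the 2 compared groups entered the fit, and 701, of which 54.9% were higher, with DESeq2. With only the compared groups the Lcn2 and Cyp4a10 calls were lost (adjusted p = 0.0679 and 0.105). The AL count was 178, 228 and 156 without scramble AL replicates 1, 3 and 5, and 185 and 582 without Ppara knockdown AL replicates 1 and 3. The IF count was 687 without Ppara knockdown IF replicate 4, and 1592 without the 6 libraries set aside.

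In livers given the Pck1 vector, transcripts of fibrosis, inflammation and cell division and tumour-associated genes were higher than in scramble livers and transcripts of hepatocyte metabolism lower. Under AL, collagens and fibrogenic genes rose in 26 of 26 cases (26 adjusted over the list alone; camera adjusted p = 9.31e-14, adjusted p = 0.217 with an estimated correlation). Col1a1, fibrillar collagen, went from 8.6 ± 2.77 to 108 ± 35.2 CPM (log2 fold change 3.65 ± 0.37, adjusted p = 9.53e-10). Markers of monocyte-derived and lipid-associated macrophages rose in 11 of 12 cases (11 adjusted over the list alone; camera adjusted p = 9.42e-08, adjusted p = 0.217 with an estimated correlation). Kupffer cell markers rose in 8 of 10 (8 adjusted over the list alone, median 0.92, camera adjusted p = 0.00786, adjusted p = 0.451 with an estimated correlation) and neutrophil markers in 6 of 6 (6 adjusted over the list alone, median 2.21, camera adjusted p = 0.0013, adjusted p = 0.248 with an estimated correlation). Trem2 changed by 4.06 ± 0.39, adjusted p = 2.07e-10 and Gpnmb by 7.20 ± 0.77, adjusted p = 2.39e-09. Liver tumour-associated genes rose in 13 of 15 cases (13 adjusted over the list alone, with 1 lower; camera adjusted p = 1.47e-07, adjusted p = 0.13 with an estimated correlation). Afp, the foetal serum protein alpha-fetoprotein (ENSMUSG00000054932; GRCm38 chromosome 5, 90490737 to 90508907, plus strand), went from 1.57 ± 0.259 to 246 ± 72.1 CPM (7.29 ± 0.43, adjusted p = 3.34e-15). H19, an imprinted non-coding RNA of foetal liver, went from 0.196 ± 0.0782 to 41.5 ± 25.8 CPM (7.72 ± 0.75, adjusted p = 2.96e-10). Proliferation genes rose in 18 of 22 cases and fell in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 3.18e-06, adjusted p = 0.248 with an estimated correlation). Mki67 changed by 2.42 ± 0.37, adjusted p = 1.54e-06. Inflammatory cytokines and receptors rose in 17 of 19 cases under AL (17 adjusted over the list alone; camera adjusted p = 9.95e-07, adjusted p = 0.248 with an estimated correlation). Hepatocyte markers fell in 7 of 9 (7 adjusted over the list alone; camera adjusted p = 0.000868, adjusted p = 0.217 with an estimated correlation), with a median log2 fold change of -0.48. With library totals alone 4 of them fell and the median was -0.125.

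Inflammatory genes were also higher in the Pck1 knockdown under IF. Of the measured inflammatory cytokines and receptors 19 of 19 rose (19 adjusted over the list alone; camera adjusted p = 3.89e-11, adjusted p = 0.178 with an estimated correlation), with a median log2 fold change of 5.09. Cxcl1, a neutrophil chemokine, went from 2.15 ± 1 to 115 ± 13 CPM (5.72 ± 0.38, adjusted p = 3.21e-14). Icam1, an adhesion molecule, went from 9.37 ± 2.01 to 141 ± 60.8 CPM (3.91 ± 0.27, adjusted p = 4.53e-14). Neutrophil markers rose in 6 of 6 cases (6 adjusted over the list alone; camera adjusted p = 5.37e-05, adjusted p = 0.178 with an estimated correlation). Macrophage markers rose in 12 of 12 (12 adjusted over the list alone; camera adjusted p = 3.88e-07, adjusted p = 0.178 with an estimated correlation). T and NK cell markers rose in 9 of 11 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0159, adjusted p = 0.396 with an estimated correlation). Collagens and fibrogenic genes rose in 26 of 26 (26 adjusted over the list alone; camera adjusted p = 2.73e-10, adjusted p = 0.222 with an estimated correlation). Saa3, an acute phase protein gene, went from 3.44 ± 1.96 to 914 ± 876 CPM (8.06 ± 0.64, adjusted p = 1.24e-12), a value that reads shared within the Saa family make uncertain. Afp changed by 7.64 ± 0.44, adjusted p = 1.04e-15. Sinusoidal endothelial markers moved the other way, with 6 of 10 lower (6 adjusted over the list alone; camera adjusted p = 0.0234, adjusted p = 0.434 with an estimated correlation). Stab2, an endothelial scavenger receptor, changed by -1.17 ± 0.14, adjusted p = 8.58e-09.

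The fall in hepatocyte transcripts after Pck1 knockdown under IF covered 8 of 9 hepatocyte markers (9 adjusted over the list alone; camera adjusted p = 0.000319, adjusted p = 0.178 with an estimated correlation). It covered 18 of 18 mitochondrial fatty acid oxidation genes (18 adjusted over the list alone; camera adjusted p = 9.15e-09, adjusted p = 0.222 with an estimated correlation). It also covered 14 of 17 genes of bile acid synthesis and transport (14 adjusted over the list alone; camera adjusted p = 1.64e-06, adjusted p = 0.179 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, went from 428 ± 106 to 30.7 ± 15.9 CPM (log2 fold change -3.80 ± 0.40, adjusted p = 6.87e-10). Cyp2e1, a hepatocyte cytochrome P450, went from 14460 ± 2040 to 3401 ± 1380 CPM (-2.09 ± 0.20, adjusted p = 1.09e-10). In gluconeogenesis and amino acid catabolism 22 of 28 genes fell and 1 rose (23 and 1 adjusted over the list alone; camera adjusted p = 1.16e-06, adjusted p = 0.275 with an estimated correlation). Hpd, a tyrosine catabolism enzyme, changed by -2.31 ± 0.19, adjusted p = 3.36e-12. Thrsp, a lipogenic regulator, changed by -4.04 ± 0.41, adjusted p = 2.39e-10. The Pck1 knockdown changed 8243 of 16651 genes under AL (4269 higher, 3974 lower) and 10353 under IF (5303 higher, 5050 lower). These directions are relative to TMM scaling: with library totals alone the median of all genes moved by 0.356 on the log2 scale under AL and by 0.356 under IF. With library totals alone 87.7% and 77.5% of calls were higher, against 51.8% and 51.2% here.

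**Figure D3:**
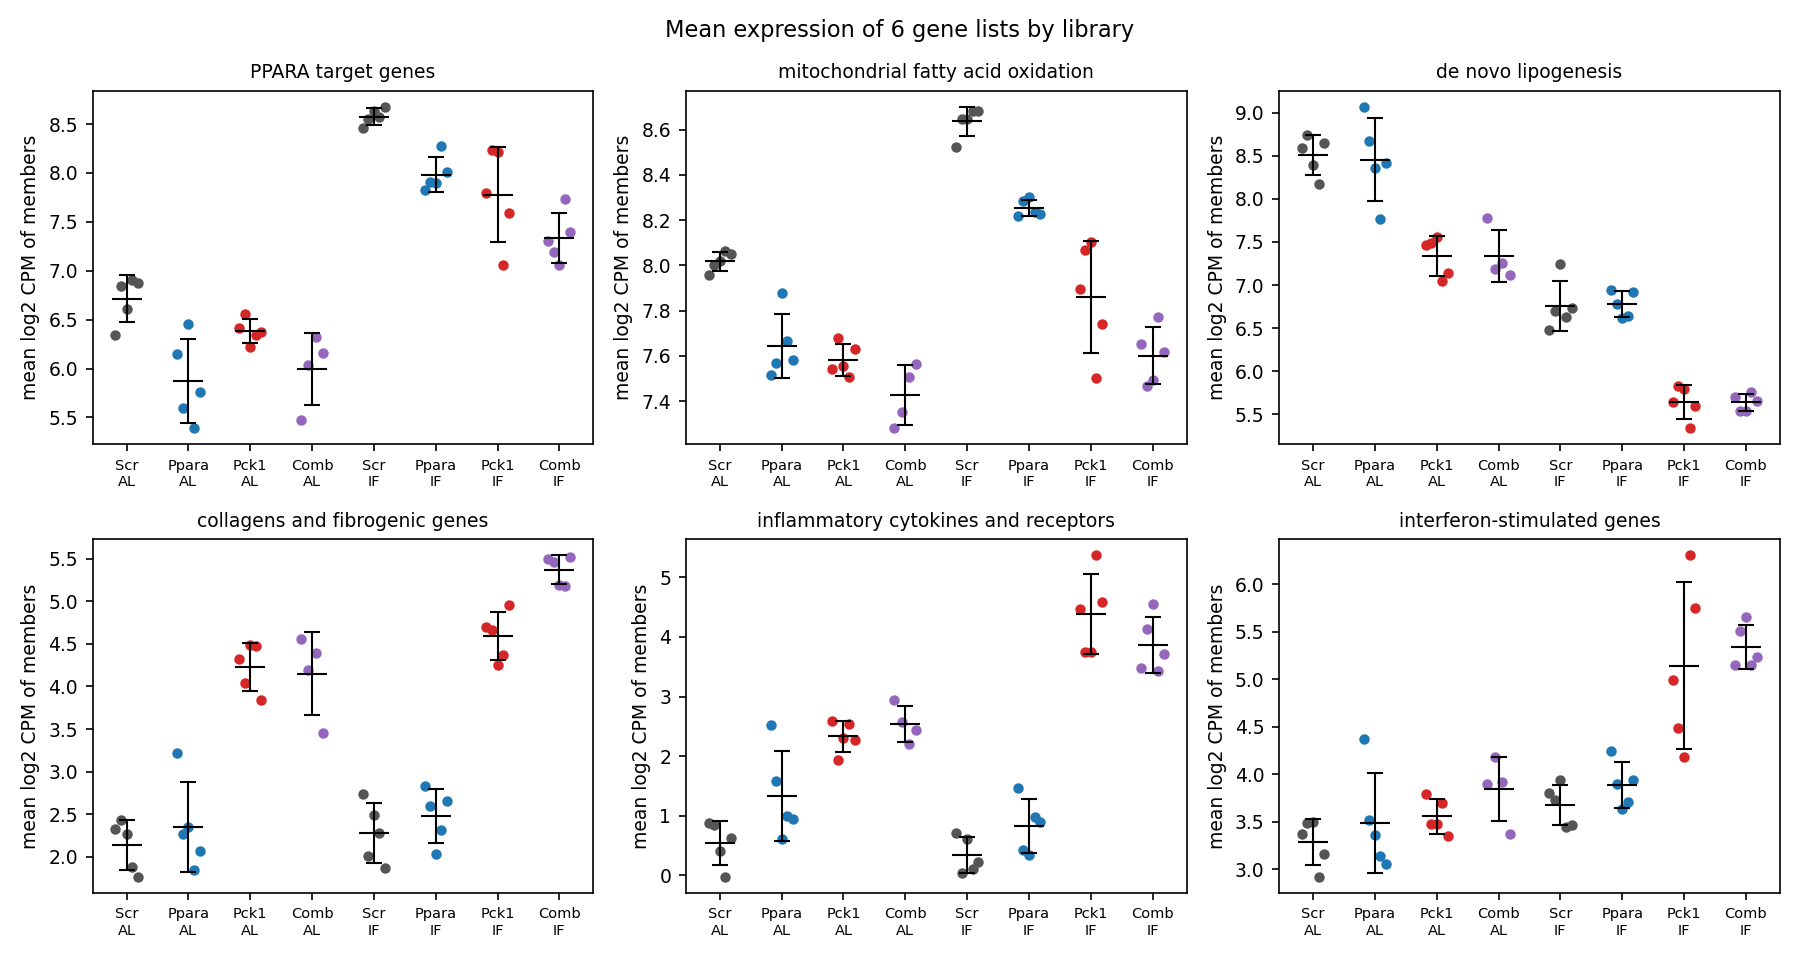
Mean log2 CPM over the members of 6 gene lists fixed before the data were examined, by vector and feeding group. Dots are libraries, horizontal marks are group means and bars are 1 SD. Median log2 fold changes of Pck1 knockdown against scramble under IF were 5.09 for inflammatory cytokines and receptors and 1.95 for collagens and fibrogenic genes.

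The combined knockdown was set against scramble in both feeding states. Under AL, collagens and fibrogenic genes rose in 26 of 26 cases (26 adjusted over the list alone; camera adjusted p = 1.23e-14, adjusted p = 0.176 with an estimated correlation). Liver tumour-associated genes rose in 13 of 15 (13 adjusted over the list alone; camera adjusted p = 6.52e-08, adjusted p = 0.115 with an estimated correlation). Afp changed by 6.12 ± 0.42, adjusted p = 4.21e-13 and Timp1, an inhibitor of matrix proteases, by 5.12 ± 0.44, adjusted p = 7.23e-11. Mitochondrial fatty acid oxidation genes fell in 18 of 18 cases (18 adjusted over the list alone; camera adjusted p = 1.52e-10, adjusted p = 0.176 with an estimated correlation), with a median of -0.60. With library totals alone 11 fell and the median was -0.282. Macrophage markers rose under AL in 11 of 12 (11 adjusted over the list alone, median 2.85, camera adjusted p = 2.13e-08, adjusted p = 0.176 with an estimated correlation), neutrophil markers in 6 of 6 (6 adjusted over the list alone, median 2.34, camera adjusted p = 0.000311, adjusted p = 0.176 with an estimated correlation) and Kupffer cell markers in 5 of 10 (7 adjusted over the list alone, median 0.97, camera adjusted p = 0.00616, adjusted p = 0.414 with an estimated correlation). The Kupffer cell count was 9 with library totals alone, and 9 with 1 lower without the 6 libraries set aside. Hepatocyte markers fell under AL in 7 of 9 (7 adjusted over the list alone, median -0.52, camera adjusted p = 0.000723, adjusted p = 0.176 with an estimated correlation), or in 3 cases with a median of -0.203 with library totals alone. Under IF, collagens and fibrogenic genes rose in 26 of 26 cases with a median log2 fold change of 2.75 (26 adjusted over the list alone; camera adjusted p = 1.71e-13, adjusted p = 0.18 with an estimated correlation). Proliferation genes rose in 21 of 22 (21 adjusted over the list alone; camera adjusted p = 2.44e-06, adjusted p = 0.245 with an estimated correlation). Interferon-stimulated genes rose in 20 of 20 (20 adjusted over the list alone; camera adjusted p = 1.05e-05, adjusted p = 0.348 with an estimated correlation). Macrophage markers rose under IF in 12 of 12 (12 adjusted over the list alone, median 3.71, camera adjusted p = 5.33e-08, adjusted p = 0.18 with an estimated correlation), neutrophil markers in 6 of 6 (6 adjusted over the list alone, median 4.28, camera adjusted p = 0.000239, adjusted p = 0.18 with an estimated correlation) and T and NK cell markers in 10 of 11 (10 adjusted over the list alone, median 1.20, camera adjusted p = 0.0365, adjusted p = 0.444 with an estimated correlation). The T and NK cell list call was lost without scramble IF replicate 1 (adjusted p = 0.0542). Lcn2 went from 10.4 ± 5.34 to 2107 ± 667 CPM (7.66 ± 0.70, adjusted p = 1.87e-11). Timp1 changed by 7.17 ± 0.43, adjusted p = 1.88e-15 and Slc7a11, the cystine transporter, by 7.96 ± 0.57, adjusted p = 6.92e-14. Hepatocyte markers fell in 9 of 9 cases (9 adjusted over the list alone; camera adjusted p = 0.000119, adjusted p = 0.18 with an estimated correlation). Hnf4a, a hepatocyte transcription factor, changed by -1.09 ± 0.12, adjusted p = 6.68e-10, or -0.66 with library totals alone. The combined knockdown changed 7236 genes under AL (3775 higher, 3461 lower) and 10741 under IF (5538 higher, 5203 lower). With library totals alone the median moved by 0.321 and 0.429, and 88.7% and 81.3% of calls were higher, against 52.2% and 51.6% here.

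In livers given the Pck1 vector, IF against AL lowered lipid synthesis and raised PPARA targets, and it also raised inflammatory transcripts. De novo lipogenesis genes fell in 19 of 22 cases (19 adjusted over the list alone; camera adjusted p = 1.67e-13, adjusted p = 0.158 with an estimated correlation). PPARA target genes rose in 15 of 22 (15 adjusted over the list alone; camera adjusted p = 4.1e-07, adjusted p = 0.234 with an estimated correlation). Thrsp changed by -6.18 ± 0.45, adjusted p = 3.46e-12. Inflammatory cytokines and receptors rose in 18 of 19 cases (18 adjusted over the list alone; camera adjusted p = 1.53e-11, adjusted p = 0.164 with an estimated correlation). Interferon-stimulated genes rose in 19 of 20 (19 adjusted over the list alone; camera adjusted p = 1.53e-11, adjusted p = 0.234 with an estimated correlation). Cxcl9, an interferon-gamma-induced chemokine, went from 10.8 ± 3.83 to 459 ± 837 CPM (5.40 ± 1.02, adjusted p = 7.56e-05). The change was 2.97 (adjusted p = 0.00301) without Pck1 knockdown IF replicate 5 and 2.13 (adjusted p = 0.0314) without the 6 libraries set aside. Immune cell markers moved with the inflammatory genes. Neutrophil markers rose in 6 of 6 cases (6 adjusted over the list alone; camera adjusted p = 6.05e-05, adjusted p = 0.164 with an estimated correlation), with a median of 2.64. T and NK cell markers rose in 7 of 11 and fell in 1 (7 and 1 adjusted over the list alone; median 1.09; camera adjusted p = 0.0151, adjusted p = 0.526 with an estimated correlation). Without Pck1 knockdown AL replicate 5 or IF replicate 5, 4 rose and 1 fell, and without the 6 libraries 4 rose and 0 fell. Macrophage markers rose in 6 of 12 (6 adjusted over the list alone, median 0.75, camera adjusted p = 0.0478, adjusted p = 0.582 with an estimated correlation), and 3 did so without Pck1 knockdown AL replicate 2 or 5, without IF replicate 5 or 6, or without the 6 libraries. The macrophage list call was lost without Pck1 knockdown AL replicate 2 or 5 (adjusted p = 0.0593 and 0.113) or IF replicate 1, 2, 3 or 6 (0.083, 0.0513, 0.0616 and 0.0557). In the combined knockdown IF raised 25 of 26 collagens and fibrogenic genes (25 adjusted over the list alone; camera adjusted p = 5.44e-11, adjusted p = 0.223 with an estimated correlation). Macrophage markers rose in 10 of 12 cases (10 adjusted over the list alone, median 1.53, camera adjusted p = 1.79e-05, adjusted p = 0.223 with an estimated correlation) and neutrophil markers in 5 of 6 (6 adjusted over the list alone, median 1.79, camera adjusted p = 0.0021, adjusted p = 0.223 with an estimated correlation). Stellate cell markers rose in 4 of 10 (4 adjusted over the list alone, median 0.38, camera adjusted p = 0.00909, adjusted p = 0.449 with an estimated correlation), a list call lost without combined knockdown AL replicate 4 (adjusted p = 0.0514) or the 6 libraries (0.0574). Hepatocyte markers fell in 3 of 9 (3 adjusted over the list alone, median -0.26, camera adjusted p = 0.00593, adjusted p = 0.223 with an estimated correlation), and the median was -0.166 with library totals alone. IF lowered 12 of 17 genes of bile acid synthesis and transport (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.62e-07, adjusted p = 0.223 with an estimated correlation). IF against AL changed 6136 genes in the Pck1 knockdown (3097 higher, 3039 lower) and 5517 in the combined knockdown (2844 higher, 2673 lower, 68% higher with library totals alone against 51.5% here). Across genes, these responses correlated with the scramble response at Pearson's r = 0.338 (Spearman's rho = 0.309) and r = 0.388 (rho = 0.324).

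The interaction tests asked whether IF acted differently in these livers than in scramble livers. In the Pck1 knockdown 3102 genes passed (1554 more positive, 1548 more negative). Unfolded protein response genes responded more positively in 14 of 16 cases (15 adjusted over the list alone; camera adjusted p = 2.71e-10, adjusted p = 0.312 with an estimated correlation). The number was 9 without the 6 libraries set aside. Pdia6, a protein disulphide isomerase, had an interaction of 1.47 ± 0.23, adjusted p = 6.02e-05. Inflammatory genes responded more positively in 11 of 19 (16 adjusted over the list alone; camera adjusted p = 4.37e-12, adjusted p = 0.31 with an estimated correlation). Cxcl1 had an interaction of 3.91 ± 0.47, adjusted p = 2.38e-06. Fga, the fibrinogen alpha chain, had an interaction of 1.73 ± 0.23, adjusted p = 9.01e-06. Interferon-stimulated genes passed in 15 of 20 cases (18 adjusted over the list alone; camera adjusted p = 7.68e-08, adjusted p = 0.502 with an estimated correlation). The number was 7 without Pck1 knockdown IF replicate 5, 6 without the 6 libraries and 2 without replicates 5 and 6 together, when the list's median went from 1.28 to 0.47. T and NK cell markers responded more positively in 5 of 11 (7 adjusted over the list alone, median 1.57, camera adjusted p = 8.88e-05, adjusted p = 0.353 with an estimated correlation) and neutrophil markers in 3 of 6 (5 adjusted over the list alone, median 2.40, camera adjusted p = 0.000162, adjusted p = 0.31 with an estimated correlation). Sinusoidal endothelial markers responded more negatively in 4 of 10 (4 adjusted over the list alone, median -0.39, camera adjusted p = 0.0096, adjusted p = 0.657 with an estimated correlation), or in 2 without the 6 libraries, and that list call was lost with fry (adjusted p = 0.0609). Cyp7a1 responded more negatively (-2.84 ± 0.52, adjusted p = 0.000378). The count over all genes was 1534 without the 6 libraries set aside. In the combined knockdown 2745 genes passed (1249 more positive, 1496 more negative, 65.7% more positive with library totals alone against 45.5% here). Gluconeogenesis and amino acid catabolism genes responded more negatively in 13 of 28 cases (18 adjusted over the list alone; camera adjusted p = 4.53e-08, adjusted p = 0.363 with an estimated correlation). Hpd had an interaction of -1.46 ± 0.27, adjusted p = 0.000378. Mitochondrial fatty acid oxidation genes responded more negatively in 10 of 18 (16 adjusted over the list alone; camera adjusted p = 4.53e-08, adjusted p = 0.363 with an estimated correlation). Unfolded protein response genes responded more positively in 8 of 16 cases (12 adjusted over the list alone; camera adjusted p = 3.19e-07, adjusted p = 0.363 with an estimated correlation). Hepatocyte markers responded more negatively in 3 of 9 (3 adjusted over the list alone, median -0.28, camera adjusted p = 0.00651, adjusted p = 0.363 with an estimated correlation), and their median was -0.172 with library totals alone. Macrophage markers responded more positively in 4 of 12 (5 adjusted over the list alone, median 1.20, camera adjusted p = 0.000212, adjusted p = 0.363 with an estimated correlation). That count was 2 without scramble AL replicate 1 or 2, combined knockdown AL replicate 1, 2 or 4, scramble IF replicate 2, 4 or 5 or combined knockdown IF replicate 2 or 3. T and NK cell markers responded more positively in 3 of 11 (3 adjusted over the list alone, median 0.84, camera adjusted p = 0.00742, adjusted p = 0.43 with an estimated correlation), or in 1 without combined knockdown AL replicate 4. Neutrophil markers did so in 2 of 6 (3 adjusted over the list alone, median 1.64, camera adjusted p = 0.00651, adjusted p = 0.363 with an estimated correlation). The neutrophil count was 0 without scramble AL replicate 1, and 1 without scramble AL replicate 2 or 5, combined knockdown AL replicate 2 or 3, scramble IF replicate 4 or combined knockdown IF replicate 2 or 3.

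Under IF the combined knockdown was set against each single knockdown. Against the Ppara knockdown it changed 10087 genes (5254 higher, 4833 lower). Collagens and fibrogenic genes were higher in 26 of 26 cases (26 adjusted over the list alone; camera adjusted p = 1.03e-13, adjusted p = 0.193 with an estimated correlation). Macrophage markers were higher in 12 of 12 (12 adjusted over the list alone, median 3.93, camera adjusted p = 8.75e-09, adjusted p = 0.185 with an estimated correlation) and neutrophil markers in 6 of 6 (6 adjusted over the list alone, median 3.94, camera adjusted p = 0.000103, adjusted p = 0.193 with an estimated correlation). Hepatocyte markers were lower in 8 of 9 (8 adjusted over the list alone; camera adjusted p = 8.18e-05, adjusted p = 0.185 with an estimated correlation) and sinusoidal endothelial markers in 6 of 10 (6 adjusted over the list alone; camera adjusted p = 0.0277, adjusted p = 0.437 with an estimated correlation), the latter list call being lost without combined knockdown IF replicate 4 (adjusted p = 0.0506). Sinusoidal endothelial markers were lower in 4 and higher in 1 with library totals alone. Afp changed by 7.09 ± 0.43, adjusted p = 3.1e-15. With library totals alone the median moved by 0.361 and 80.5% of those calls were higher, against 52.1% here. Against the Pck1 knockdown it changed 335 genes (189 higher, 146 lower). Col1a1 went from 85.2 ± 26 to 226 ± 47.7 CPM (1.41 ± 0.34, adjusted p = 0.0237). Acta2, the smooth muscle actin of activated stellate cells, went from 3.44 ± 1.38 to 11.4 ± 4.62 CPM (1.73 ± 0.39, adjusted p = 0.0155). Collagens and fibrogenic genes were higher in 11 of 26 cases (17 adjusted over the list alone; camera adjusted p = 4.32e-15, adjusted p = 0.3 with an estimated correlation). They were higher in 6 cases without Pck1 knockdown IF replicate 3 or 5 or combined knockdown IF replicate 1, and 5 without combined knockdown IF replicate 5. Proliferation genes were higher in 4 of 22 (14 adjusted over the list alone, median 0.84, camera adjusted p = 2.25e-13, adjusted p = 0.3 with an estimated correlation), or in 9 without the 6 libraries set aside. Camera also called macrophage markers (median 0.67; camera adjusted p = 0.00151, adjusted p = 0.791 with an estimated correlation) and stellate cell markers (median 0.32; camera adjusted p = 0.0114, adjusted p = 0.791 with an estimated correlation) higher. Neither was called with fry (adjusted p = 0.267 and 0.44), and the stellate cell call was lost without combined knockdown IF replicate 2 or 3 (adjusted p = 0.066 and 0.0509). Fat oxidation transcripts were lower: 8 mitochondrial fatty acid oxidation genes and 3 PPARA target genes passed the threshold, and 0 of either list were higher. These counts were 13 and 11 without the 6 libraries set aside, and 3 and 1 without Pck1 knockdown IF replicate 2 or 3. Camera called the PPARA target list, a call lost with fry (adjusted p = 0.204) and with an estimated correlation. Ppara itself was lower in the combined knockdown (-0.68 ± 0.13, adjusted p = 0.00529, or -1.07 with effective-length offsets), although its call was lost when only the compared groups entered the fit (adjusted p = 0.0826). Pck1 differed by 0.14 ± 0.28 (adjusted p = 0.862). The Col1a1 call was lost without Pck1 knockdown IF replicate 3 or 5 or combined knockdown IF replicate 1 or 5 (adjusted p = 0.0643, 0.0522, 0.0684 and 0.0614). The Acta2 call was lost without combined knockdown IF replicate 5 (adjusted p = 0.0566). The count of 335 was 202 and 187 without Pck1 knockdown IF replicates 1 and 3, and 87, 212 and 169 without combined knockdown IF replicates 1, 2 and 5. It was 197 with no count filter and 701 with DESeq2. The count was 1346 without the 6 libraries set aside, with 41.5% of calls higher, against 56.4% here. The share was 85.8% with library totals alone and 86.1% with only the compared groups in the fit.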

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

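The tests of cell composition, of remaining Pck1 or Ppara transcript, of the interval of the Ppara knockdown interaction and of immune cell markers were chosen after their results or closely related values had been seen. The 2 libraries set aside in the interferon test were picked from principal components, before that test's value was seen.

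Of 352 group values examined for 1 library far from the others of its group, 17 were found, against 17.6 by chance at 1 in 20. Ppara knockdown AL replicate 1 accounted for 7 of them: its 10 top genes held 18.37% of counts, principal component 1 was -4.59, and mean log2 CPM was 8.10 for bile acid synthesis and transport, 5.80 for NRF2 targets, 3.37 for p53 targets, 1.75 for proliferation and 3.19 for macrophage markers. Ppara knockdown AL replicate 4 stood apart in acute phase genes (9.40). In scramble AL, replicate 4 stood apart in the unfolded protein response (8.04) and replicate 2 in mitochondrially encoded genes (11.31). In scramble IF, replicate 1 stood apart in mitochondrial fatty acid oxidation (8.52) and replicate 3 in cholesterol synthesis (4.29). Pck1 knockdown AL replicate 3 had 17.11% of counts in its 10 top genes, and replicate 2 a mean log2 CPM of 0.13 for neutrophil markers. The total of Pck1 knockdown IF replicate 3 was 43.74 M, and genes with a count numbered 19635 in combined knockdown AL replicate 4 and 20011 in Ppara knockdown IF replicate 1.

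Effects of IF that differed between scramble and a knockdown were found by the interaction test: 3 genes for Ppara, 3102 for Pck1 and 2745 for the combined knockdown. At the level of lists, camera called the following median log2 interactions. In the Ppara knockdown they were -0.87 for acute phase genes, 0.13 for mitochondrially encoded genes, -0.49 for Kupffer cell, -0.77 for macrophage, 0.48 for stellate cell and -0.61 for neutrophil markers. In the Pck1 knockdown they were -0.34 for mitochondrial fatty acid oxidation, -0.33 for gluconeogenesis and amino acid catabolism, 0.33 for cholesterol synthesis, -0.41 for bile acid genes, 1.12 for the unfolded protein response, 0.77 for p53 targets, 1.28 for interferon-stimulated genes, 1.16 for acute phase genes, 2.43 for inflammatory genes, -0.58 for male-biased liver genes, -0.39 for sinusoidal endothelial, 1.57 for T and NK cell and 2.40 for neutrophil markers. In the combined knockdown they were -0.51 for PPARA target genes, -0.47 for mitochondrial fatty acid oxidation, -0.81 for gluconeogenesis and amino acid catabolism, 0.28 for cholesterol synthesis, -0.60 for bile acid genes, 0.99 for the unfolded protein response, 0.70 for p53 targets, 1.07 for interferon-stimulated genes, 0.66 for acute phase genes, 1.69 for inflammatory genes, 1.01 for collagens and fibrogenic genes, 0.42 for proliferation, 0.78 for tumour-associated genes, -0.76 for male-biased genes, -0.28 for hepatocyte (-0.172 with library totals alone), 1.20 for macrophage, 0.84 for T and NK cell and 1.64 for neutrophil markers. None of these list calls held with an estimated correlation, and in the Ppara knockdown none held with fry (adjusted p = 0.936 for each). Fry also ended the calls of gluconeogenesis, cholesterol synthesis, male-biased and sinusoidal endothelial genes in the Pck1 knockdown (adjusted p = 0.0698, 0.0698, 0.121 and 0.0609). In the combined knockdown it ended those of PPARA target, cholesterol synthesis, proliferation and male-biased genes (0.0765, 0.142, 0.162 and 0.0566). Without single libraries, 4 of the 6 Ppara knockdown list calls were lost. The Kupffer cell call was lost without scramble AL replicate 1, 3, 4 or 5, Ppara knockdown AL replicate 1 or 2, scramble IF replicate 1 or 4 or Ppara knockdown IF replicate 2, 3 or 4 (adjusted p = 0.0524 to 0.537). The macrophage call was lost without scramble AL replicate 4, Ppara knockdown AL replicate 1, scramble IF replicate 1 or Ppara knockdown IF replicate 3 (0.0588 to 0.409). The neutrophil call was lost without scramble AL replicate 3 or 4, Ppara knockdown AL replicate 1, 2 or 4, scramble IF replicate 1 or 2 or Ppara knockdown IF replicate 2, 3 or 4 (0.0655 to 0.294). The mitochondrially encoded call was lost without scramble AL replicate 4, Ppara knockdown AL replicate 1, scramble IF replicate 1 or 3 or Ppara knockdown IF replicate 3 (0.0559 to 0.294). Without the 6 libraries set aside these 4 had adjusted p = 0.543, 0.656, 0.532 and 0.195. The male-biased call of the Pck1 knockdown was lost without scramble AL replicate 2, Pck1 knockdown AL replicate 5, scramble IF replicate 2, 4 or 5 or Pck1 knockdown IF replicate 5 or 6 (0.0626 to 0.18) and without the 6 libraries (0.426), which also ended its gluconeogenesis call (0.112). In the combined knockdown the cholesterol synthesis call was lost without scramble AL replicate 1 or 2, combined knockdown AL replicate 4, scramble IF replicate 1 or 5 or combined knockdown IF replicate 1 or 4 (0.0505 to 0.166). Its proliferation call was lost without scramble AL replicate 1, combined knockdown AL replicate 1 or 4, scramble IF replicate 2 or combined knockdown IF replicate 1 (0.0522 to 0.0999) and without the 6 libraries (0.0779).

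The broad difference of Pck1 knockdown from scramble livers under IF covered 10353 genes. A lower share of hepatocytes alone would raise the markers of every other cell type alike, but the mean log2 change of macrophage markers exceeded that of sinusoidal endothelial markers by 4.21 (nominal 95% interval 3.45 to 4.87), which argues against it as the whole account, while a change in the immune cells themselves stays open. Depth was also argued against: 10123 genes were called after thinning every library to the smallest total. With library totals alone 4554 genes changed at least 2-fold, against 4061, so TMM scaling did not create the number of large changes. That count cannot address direction, which did depend on scaling: 77.5% of all calls were higher with library totals alone, against 51.2%. Loss of Pck1 and another effect of that vector cannot be told apart, because each target had a single vector. Gene counts do not decide it: under AL the combined knockdown, with a higher mean Pck1, changed 7236 genes against 8243. Those groups had 4 and 5 libraries. Their Pck1 overlapped, at 457.2 to 872.5 CPM in the combined and 218.9 to 579.5 in the Pck1 knockdown, and was not tested between them. A biological effect of lower Pck1 may account for the broad difference from scramble and stays open as a hypothesis.

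Interferon-stimulated genes responded to IF more positively in the Pck1 knockdown than in scramble, with a median of 1.28. Without Pck1 knockdown IF replicates 5 and 6 the median was 0.47 and 2 of 20 genes passed, although camera still called the list (adjusted p = 0.000148), so much of the size of this pattern may rest on those libraries. They also had the lowest Pck1 of their group, 555.2 and 494.5 CPM against 972.4 to 1168 in the others. Their Ppara was lowest too, at 56.96 and 63.92 CPM against 85.1 to 109.7. Leaving them out therefore also removed the lowest levels of both transcripts, which this test cannot separate from libraries that stand apart. Whether the knockdown itself was deeper in them was not tested. The list exceeded the macrophage markers by 0.67 (nominal 95% interval -0.21 to 1.67) in the same interaction, and minus the T and NK cell markers the difference was -0.27 (-0.96 to 0.47). Because both intervals include 0, more of these cells and a response within cells cannot be told apart. Neutrophil markers rose more than the list, with a difference of -0.86 (-1.55 to -0.17), so more neutrophils may also contribute.

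PPARA target genes rose with IF in Ppara knockdown livers. Too few libraries to see a lost response was argued against: the mean interaction was 0.25 and its nominal 95% interval, -0.17 to 0.65, lay above -0.93, the interaction at which the knockdown response would be as far from the scramble response of 1.86 as from 0. The knockdown left 44.7% of the transcript, and activity of the remaining PPARA protein may account for the response, which cannot be told apart from activation of these genes by another route because no group had a deeper loss with intact Pck1.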

How the results depend on the processing

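Library totals alone as scaling and the omission of 6 libraries set aside by eye were chosen after seeing the data, and the other alternatives before. For IF against AL in each vector, Pck1 or combined knockdown against scramble, the combined knockdown interaction and the combined against the Ppara knockdown, the count of changed genes stayed within 1.5 times under every alternative run. For Ppara knockdown against scramble under AL the count of 354 was 222 with library totals alone, 52 with only the compared groups and 701 with DESeq2, and 156 to 582 without single libraries. Under IF the count of 1045 was 1592 without the 6 libraries and 687 to 1046 without single libraries. The 3 interaction genes of the Ppara knockdown became 0 with no filter, effective-length offsets, library totals alone or only the compared groups, 6 with the filter at a mean of 1 CPM, 27 without the 6 libraries, 30 with DESeq2 and 0 to 10 without single libraries. The Pck1 interaction count of 3102 was 1534 without the 6 libraries. The combined against Pck1 knockdown count of 335 was 197 with no filter, 1346 without the 6 libraries and 701 with DESeq2, and 87 to 474 without single libraries. With an estimated correlation the 190 pathway list calls became 3 and the 53 cell type calls became 0. The cause of these changes was not tested. Omitting libraries or groups also leaves fewer samples, although counts such as the 335 rose, to 1346, without the 6 libraries. Of the genes named, 63 values under an alternative lost their call and 1114 kept their direction and side of the threshold. The Pck1 difference of combined against Pck1 knockdown, which was not called, was 0.14 and turned to -0.209 without the 6 libraries, and ranged from -0.022 (without Pck1 knockdown IF replicate 6) to 0.274 (without replicate 2) without single libraries. For the Pck1 knockdown under IF, thinning to 43.74 M gave 10123 calls against 10353, and no other comparison was thinned.

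Replicate numbers did not pair the libraries consistently: in no contrast did every same-numbered pair correlate above 0.1. Single pairs ranged from -0.346 (replicate 3, combined against Pck1 knockdown, IF) to 0.43 (replicate 1, IF against AL, Ppara knockdown). Pairing of some libraries therefore cannot be excluded. With the replicate block the combined against Pck1 knockdown count became 595, and no other count moved by over 1.5 times. In the scramble IF against AL contrast 2 of 5 libraries correlated best with their own number.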

Other observations

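The lists were fixed before the data were examined, but those described here were picked after their results had been seen, while the splits of the libraries were planned before their counts were seen. Male-biased and stress lists moved in single comparisons too, outside the interactions. The labels do not give the sex of the mice. Against scramble under IF, male-biased liver genes fell in 10 of 12 cases in the Pck1 knockdown (10 adjusted over the list alone; camera adjusted p = 0.00298, adjusted p = 0.395 with an estimated correlation) and in 10 of 12 in the combined knockdown (10 adjusted over the list alone; camera adjusted p = 0.00166, adjusted p = 0.348 with an estimated correlation). Hepatocyte markers fell in the same comparisons (medians -0.84 and -1.09, or -0.487 and -0.663 with library totals alone), and female-biased liver genes, of which 8 were measured, went both ways, with 2 higher and 3 lower in the Pck1 knockdown (camera adjusted p = 0.697) and 1 higher and 3 lower in the combined knockdown (camera adjusted p = 0.625). Targets of p53, the damage-response transcription factor, rose in 10 of 12 cases in the Pck1 knockdown (10 adjusted over the list alone; camera adjusted p = 1.67e-05, adjusted p = 0.178 with an estimated correlation) and in 10 of 12 in the combined knockdown (10 adjusted over the list alone; camera adjusted p = 3.89e-05, adjusted p = 0.18 with an estimated correlation). Genes of NRF2, which controls antioxidant enzymes, rose in 11 of 13 cases in the Pck1 knockdown under AL and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 4.66e-05, adjusted p = 0.248 with an estimated correlation). In scramble livers IF lowered 7 of 16 unfolded protein response genes (7 adjusted over the list alone; camera adjusted p = 0.000171, adjusted p = 0.607 with an estimated correlation), a count that was 3 without scramble AL replicate 4 and 4 without scramble IF replicate 1.

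For the splits, the contrasts were refitted on the compared groups alone, so the real counts differ from those of the 39-library model. Among 40 splits per contrast, the real one included, only the real one gave as many genes for the following contrasts. That share of 1 in 40 is the lowest that 40 splits can give, and it was not corrected over the contrasts. For IF against AL the real count and the highest other were 3622 and 15 in scramble, 3453 and 9 in the Ppara knockdown, 5589 and 1 in the Pck1 knockdown and 5474 and 2991 in the combined knockdown. Against scramble they were 52 and 2 (AL) and 806 and 5 (IF) for Ppara, 8193 and 2 (AL) and 9363 and 0 (IF) for Pck1, and 6743 and 1525 (AL) and 10295 and 0 (IF) for the combined knockdown. They were 2748 and 2315 for the Pck1 interaction, 3131 and 0 for the combined interaction and 9554 and 0 for the combined against the Ppara knockdown. For the interactions, vector labels were exchanged within each feeding state. Those splits therefore test for any effect of the vector and cannot decide on a difference between the IF responses. For the Ppara interaction the splits decide nothing, because the real split called 0 genes in this fit and all 40 splits necessarily called as many (the highest other called 40). Chance could not be excluded for the combined against the Pck1 knockdown, where 2 of 40 splits gave as many as the real 295 and the highest other called 951, which points to a structure among those libraries.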
